A study of Mus musculus with 2 samples.

How the data were processed

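Poly(A) RNA was measured in 2 libraries of pSM44 mouse embryonic stem cells, both labelled as treated with doxycycline for 24 h. Per the labels' protocols, total RNA was column-purified, and poly(A) RNA was taken through repeated capture on oligo-dT beads. It was then fragmented, ligated to a single-stranded RNA adaptor, reverse-transcribed, ligated to another adaptor, amplified and sequenced on a HiSeq instrument. Trimmomatic 0.38, HISAT2, SAMtools and featureCounts of Subread 1.6.4 were used with the GRCm38.p6 build, per the submitters' processing notes. The annotation release, the strand setting and whether exons or whole genes were counted are not given in the sources used here.

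The authors deposited raw counts per gene symbol, in a single column for protein-coding genes with at least 1 count. The column held whole numbers from 1 to 117610 that summed to 10017978. It named the line and the treatment but not a library, so it was used as 1 value per gene for the group. Rows followed the count per base of gene span (Spearman rho across genes 0.9999). Gene symbols were matched to GENCODE M21 on GRCm38, the assembly of the authors' build, which gave 14879 matches, and RefSeq synonyms gave 181 more. The 67 unmatched symbols held 0.327% of the counts and had no position. M21 annotates 22028 protein-coding genes, and 15060 of them were in the table. As the authors' annotation may differ, overlap and length values here are those of M21.

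Counts were scaled by the total to CPM and logged as log2(CPM + 1). A gene was called detected at CPM 1 or more. Single counts had exact Poisson 95% intervals and shares had exact Clopper-Pearson 95% intervals. Both cover counting error only, since reads without molecular identifiers are not independent molecules. Medians and their ratios had 95% intervals from 2000 bootstrap draws of genes (1000 for the tests on chromosomes 8 and 16), which describe gene sampling and not replicate error. Each list median was placed among 10000 random lists of the same size. Chromosome groups were compared with exact permutation tests over chromosomes. Exonic overlap was the share of a gene's exonic bases under the span of another annotated gene, and a gene with at most 0.1 was called overlap-free. A gene whose whole span lay in another gene's span was called nested.

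The 44 gene lists and symbol patterns, the tests of the main comparisons and the rule for naming genes were fixed before the data were examined. The comparison of LIF and ERK targets and several tests of explanations were chosen later. The rule named the 20 highest genes, the 3 highest members and the lowest detected member of each list, and any member of the core, naive, formative and primed, and Y-linked lists. Not every gene that the rule names is reported here. Some further members of lists were named after their values were seen, among them Sox1, Tubb3, Srsf2, Matr3, Egr1 and members not listed in the table. The lists covered pluripotency states, lineages and other cell types, signalling targets, chromatin and nuclear bodies, Xist-linked factors, sex chromosomes, stress, cell cycle, housekeeping and large gene families.

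Agreement between the 2 libraries, their biological variation, genes that differ 2-fold between them and scaling between libraries had been planned with count models. They were not run because the counts had 1 column. The alternatives tried were other CPM minimums (0.5, 5 and 10 counts), a pseudocount of 0.1, counts per kilobase of exon, no minimum, another centromere window of 20 Mb and removal of receptor, defensin and keratin-associated families. After the data were seen, overlap-free genes only, unlisted members at 0, and shares over pooled genes in place of means over chromosomes, were added.

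The functions were tested on simulated counts drawn from the listed genes. A list of 200 genes raised 4-fold had a median log2 change of 1.94 among 15058 genes. X-linked genes halved in level gave a ratio of 0.526 over 582 genes, and chromosome 8 raised 1.5-fold gave 1.54 over 756 genes. Both ratios were relative to an unchanged draw and covered all listed genes without a CPM minimum. The main chromosome ratios in the results used genes at CPM 1 or more, so the simulation did not test that filter. With 5 chromosomes lowered by 10 percentage points, 100% of 40 draws passed 0.05, against 7.5% of 40 draws with no difference. For the paired test, 98% of 100 draws with a planted difference of 10 points and a standard deviation of 10 passed, against 8% with none. The draws of 5 chromosomes held counting noise only, whereas real shares ran from 45.8% (chromosome 14) to 64.9% (chromosome 12). Real shares near the centromere also varied widely, with 10.1% against 51.2% for the rest on chromosome 14. These rates therefore do not give the power of the tests on the real data. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.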

Results

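The series from which these RNA libraries came mapped genome structure together with nascent RNA, and the poly(A) RNA measured here describes the steady-state transcripts of the same kind of cell. The cells were pSM44, a female mouse embryonic stem cell line from a cross of the 129 and castaneus strains. In this line Xist, the long non-coding RNA that silences an X chromosome, is switched on from its own locus on the 129 chromosome by doxycycline. Both libraries belonged to 1 group, kept for 24 h with doxycycline at 2 μg/mL in serum-free 2i/LIF medium, which holds cells in a naive state with 2 kinase inhibitors and the cytokine LIF. The counts were a single column of 15127 protein-coding genes with 10017978 counts in total. Whether that column pooled both libraries or held 1 of them is not given in the sources used here, so each gene had 1 value and no replicate error could be computed. The smallest count listed was 1, so a gene that was not listed is described as such and not as silent. No untreated cells were analysed here, so none of the values measures a response to doxycycline or to Xist.

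Raw counts, which grow with transcript length, were highest for Eef1a1, followed by chaperone, actin, elongation factor and ribosomal protein genes and Dppa5a. Eef1a1, the translation elongation factor that delivers aminoacyl-tRNA, had 117610 counts, or 11740 CPM (the count scaled by the library total; 95% Poisson interval 11673 to 11807). The chaperone genes Hsp90ab1 and Hsp90aa1 followed with 73402 and 62061 counts. Actb had 47435 counts, Eef2 had 47313 and Dppa5a, a gene typical of pluripotent cells, had 47245. Among the 20 genes with the highest counts, 8 encoded ribosomal proteins, led by Rpl4 with 36543. The others of the 20 were Atp5b, Tubb5, Rack1, Pabpc1, Hspa8 and Npm1, the last with 22428 counts. Per kilobase of exon, Dppa5a came first and Eef1a1 after it. Together the 20 genes held 7.67% of the counts. At CPM 1 or more, which took 11 counts, 12119 genes were detected. Of these 8910 were at CPM 10 or more, 2352 at 100 or more and 96 at 1000 or more, while 866 genes had exactly 1 count. The median listed gene was at CPM 18.3. The Poisson intervals cover counting error only, with a half-width of 64.5% of the value at CPM 1 and 6.25% at 1000 counts.

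Genes of the naive pluripotent state were abundant, and genes of the later formative and primed states were lower as a group. All 18 listed naive genes were at CPM 1 or more, with a median CPM of 207, against 22.4 for 15 listed formative and primed genes. Dppa5a stood highest among the naive genes, followed by Esrrb with 7172 counts, Klf2 with 5379, Tfcp2l1 with 5178 and Zfp42 with 4742. Klf4 had 3123 counts, Dppa3 2328, Prdm14 1093 and Nr5a2 815, and the lowest naive gene was Spic with 289. Among formative and primed genes, Fgf5, a marker of the post-implantation epiblast, had 1 count, and Otx2 had 84. Pou3f1 had 74 counts and Dusp6 15, whereas the Nodal antagonist Lefty2 had 3614. The de novo methyltransferase genes Dnmt3a and Dnmt3b had 1017 and 725 counts, and Cer1 and Wnt8a were not listed. The naive median lay 3.15 above the formative and primed median on the log2(CPM + 1) scale, with a bootstrap 95% interval over genes of 1.19 to 4.93. As a description of these libraries, that difference was at percentile 98.5 among 10000 pairs of random lists of the same sizes.

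**Figure D1:**
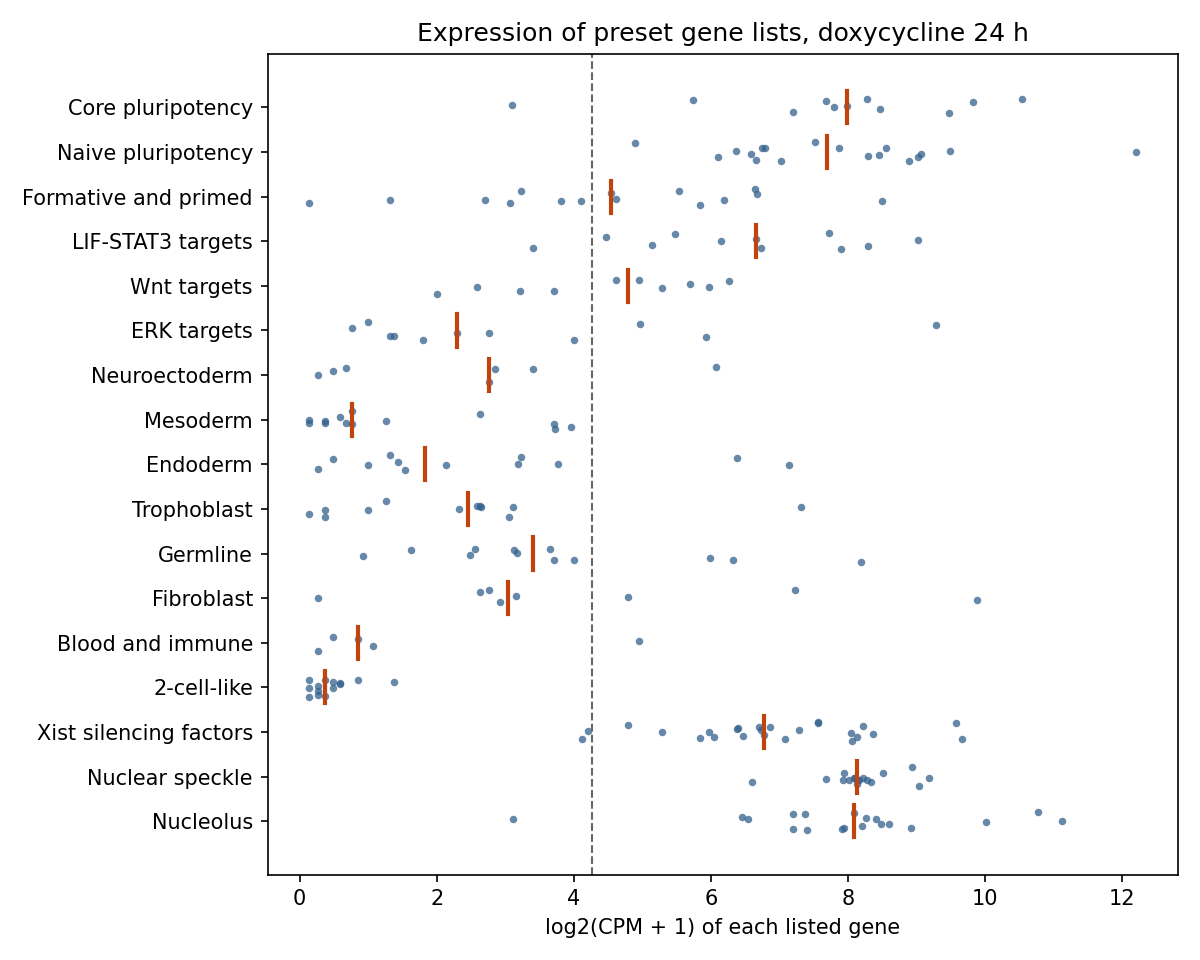
Each point is 1 listed gene of a preset gene list, on a scale of log2(CPM + 1). Orange bars are list medians and the dashed line is the median of all listed genes (CPM 18.3). The naive pluripotency median (CPM 207) lies above that line, and the mesoderm, endoderm and 2-cell-like medians lie below it.

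Core pluripotency genes stood with the naive ones and far above markers of differentiated lineages. Nanog had 9026 counts, Pou5f1, which encodes the transcription factor Oct4, had 7100, and Trim28, a corepressor of endogenous retroviruses, had 14919. Sall4 had 2052 counts, Utf1 2219 and Fgf4 3096, whereas Lin28a had 76. Sox2 was not listed. The annotation places it at chromosome 3, 34650405 to 34652461 (GRCm38), wholly inside the non-coding gene Sox2ot. Of 30 annotated core and naive genes, 29 were at CPM 1 or more. The lineage markers pooled the neuroectoderm, mesoderm, endoderm, trophoblast, germline, fibroblast and blood lists. Of these 94 annotated genes, 44 were at CPM 1 or more, and 27 were not listed, 5 of which lay inside another gene. The 29 listed core and naive genes had a median CPM of 232 and the 67 listed lineage markers 4.99. The medians differed by 5.28 on the log2 scale (bootstrap 95% interval 4.40 to 6.82), which exceeded all 10000 random pairs (percentile 100).

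The lineage lists were not uniformly low, and their medians cover listed members only, so they do not rank the lists. The mesoderm list had a median CPM of 0.699, with 5 of 14 annotated genes at CPM 1 or more, led by Gsc with 146 counts and Twist1 with 122. Endoderm genes had a median CPM of 2.65, with 9 of 14 at CPM 1 or more, and their highest members were the basement membrane genes Lama1 and Col4a1 with 1400 and 825 counts, then Gata4 with 127. In the neuroectoderm list 4 of 14 annotated genes were at CPM 1 or more and 7 were not listed. Nes had 662 counts, Gbx2 96 and Pax6 62, and the median over the 7 listed members was 5.79. Its members Sox1, Tubb3 and Neurod1 were not listed and lay inside other genes. Trophoblast genes had a median CPM of 4.49, with 8 of 14 at CPM 1 or more, led by Tfap2c with 1582 counts, Krt8 with 77 and Krt18 with 73. Germline genes reached a median of 9.78, with 11 of 13 at CPM 1 or more, led by Dazl with 2909 counts, then Rhox6 and Rhox9, uncertain because of their near-identical relatives, with 794 and 626. In the fibroblast list, Fn1 had 9451 counts, Vim 1487 and Thy1 267, while 7 of 15 genes, Col3a1 and Dcn among them, were not listed. The blood and immune list had 2 of 12 genes at CPM 1 or more, the highest being Cd68 with 301 counts. A list of muscle, liver and other organ markers also had 2 of 12, led by Des with 148 counts. The 2-cell-like list, whose members have near-identical copies and are uncertain, had 1 gene at CPM 1 or more, Usp17le with 16 counts.

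Targets of the pathways that the medium acts on differed in level. Genes activated by LIF through STAT3 had a median CPM of 99.5, all 11 of them at CPM 1 or more. Tfcp2l1 and Klf4 were again the highest, then the kinase gene Pim3 with 2385 counts. Targets of ERK signalling, which one of the inhibitors blocks, had a median CPM of 3.89, with 9 of 12 annotated genes at CPM 1 or more. Among them Etv5 stood apart with 6222 counts, against 602 for Spred2, 304 for Spred1 and 7 for the immediate early gene Egr1. The LIF and STAT3 median lay 4.36 above the ERK median on the log2 scale (bootstrap 95% interval 1.48 to 6.35), a comparison chosen after the values were seen. Per kilobase of exon the difference was 2.88. Wnt targets, in a pathway that the other inhibitor activates, had a median CPM of 26.8 with 10 of 11 genes at CPM 1 or more. The highest were Tcf7, whose exons lie under another gene, with 759 counts, Ccnd1 with 621 and Sp5 with 511. DNA methylation genes had a median CPM of 102, led by Uhrf1 with 6420 counts, Dnmt1 with 3913 and the imprint regulator Zfp57 with 2295, and lowest at Dnmt3l with 56.

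Genes of nuclear bodies and chromatin complexes were nearly all expressed. Of 141 annotated genes in the nuclear lists, 138 were at CPM 1 or more, and the 139 listed ones had a median CPM of 146. Their median exceeded that of all 15127 listed genes by 2.93 on the log2 scale (bootstrap 95% interval 2.46 to 3.26; percentile 100 of 10000 random lists). That height is not particular to nuclear genes. The same difference was 2.77 for nuclear genes of oxidative phosphorylation, 2.52 for p53 targets and 4.03 for cell cycle genes. Nuclear speckle genes, which encode splicing factors, had a median CPM of 278, led by Prpf8 with 5801 counts, Srrm2 with 5271 and Srrm1 with 4898. The splicing factor gene Srsf2, inside Mettl23, was not listed. Nucleolar genes had a median of 272, led by Npm1, Ncl with 17587 counts and Mybbp1a with 10360, and lowest at Taf1a with 77. Lamina genes had a median CPM of 65.9, with Lmnb1 at 4485 counts, Lbr at 3297 and Banf1 at 3234. Cajal and histone locus body genes had a median of 74.2, led by Coil with 2728 counts and Gemin5 with 1428. RNA polymerase II and elongation genes had a median CPM of 95.03, led by Polr2e with 3331 counts and Polr2a with 3103. Cohesin, condensin and CTCF genes had a median of 158, led by Rad21 with 4614 counts and Smc4 with 4093.

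Repressive chromatin genes followed the same range. The core of Polycomb repressive complex 2, which methylates histone H3 lysine 27, had a median CPM of 181, led by Rbbp4 with 6048 counts, Suz12 with 5194 and Rbbp7 with 4607. Polycomb repressive complex 1 genes had a median of 60.6, led by Phc1 with 2620 counts and Pcgf6 with 1147, and lowest at Cbx8 with 43. Heterochromatin genes had a median CPM of 120, led by Trim28, the methyltransferase gene Ehmt2 with 2990 counts and Atrx with 2623. Suv39h1 had 4 counts, and nearly its whole exonic length lay under another gene. Factors tied to Xist-mediated silencing had a median CPM of 109, and all 25 listed ones were at CPM 1 or more. Hnrnpu, which anchors Xist RNA, had 8076 counts, Hnrnpk 7650 and Lbr 3297, and the lowest was Ciz1 with 165. Matr3 was not listed and was fully covered by another annotated gene.

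Few members of large families with roles in other organs reached CPM 1, and most that did were Hox genes and keratins. Of 1710 annotated members of 7 families, 28 were at CPM 1 or more, or 1.64% (Clopper-Pearson 95% interval 1.09 to 2.36). Over all annotated genes the share was 54.9%. Olfactory receptors gave 5 of 1135, led by Olfr66 with 108 counts, Olfr77 with 60 and Olfr814 with 35. Vomeronasal receptors gave 3 of 331, led by Vmn1r88 with 25 counts, Vmn2r1 with 19 and Vmn2r59 with 15. No beta-defensin gene of 42 and no keratin-associated protein gene of 57 reached CPM 1, the highest being Defb30 with 3 counts and Krtap5-5 with 1. Keratins gave 7 of 49, led by Krt42 with 201 counts, Krt8 with 77 and Krt18 with 73. Hox genes, which pattern the body axis, gave 13 of 39, led by Hoxc13 with 218 counts, Hoxa10 with 167 and Hoxc4 with 144. Of the 39 Hox genes, 12 lay inside another gene. Among Hox genes nearly free of overlap with others, 11 of 18 were at CPM 1 or more (61.1%, interval 35.7 to 82.7). That share is near the 57.7% of all overlap-free annotated genes, but the level was low. The 23 listed Hox genes had a median CPM of 2.20, against 18.3 for all listed genes. Among overlap-free genes, the Hox median minus that of all genes was -2.60 on the log2 scale. None of 57 clustered protocadherin genes was listed, and 55 of them lay inside another gene.

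Counts of transcripts that normally lack a poly(A) tail were low. The 50 listed replication-type histone genes, uncertain because of near-identical copies, summed to 578 counts, or 0.00577% of the total (Clopper-Pearson 95% interval 0.00531 to 0.00626). The highest was H1f2 with 118 counts. Of 67 annotated histone genes of this type, 17 were not listed, 7 of which lay inside another gene. Exonic overlap exceeded 0.1 in 23 of the 67, so these counts do not separate poly(A) capture from losses in counting. The 80 listed ribosomal protein genes, whose processed copies make single values uncertain, held 9.78% of the counts. The 92 listed nuclear genes of oxidative phosphorylation held 2.05%, led by Atp5b with 29637 counts, Atp5a1 with 17761 and Atp5g3 with 7720. None of the 13 annotated mitochondrially encoded genes was listed. Whether they were left out of the table is not given in the sources used here, so their absence says nothing about poly(A) capture.

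Y-linked genes were close to absent in this line, which is labelled female. Only 2 Y-linked genes were listed, Usp9y with 1 count and Gm21693 with 4, out of 183 annotated. Gm21693 lies outside the preset list and was named after its value was seen. Ddx3y, Eif2s3y, Kdm5d and Uty were not listed. X-linked genes with broad expression had a median CPM of 180, led by Rps4x (chromosome X, 102184941 to 102189394) with 24130 counts, Pgk1 with 5940 and Ddx3x with 5264. Rbmx was the lowest with 39 counts, and G6pdx, inside Ikbkg, was not listed.

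Detected X-linked genes as a set were near the autosomal level, while detected genes of chromosomes 8 and 16 were higher. Of 948 annotated X-linked genes, 47.2% were at CPM 1 or more (Clopper-Pearson 95% interval 43.9 to 50.4), against 54.9% of all annotated genes. Only chromosomes 7 (47.0%) and 14 (45.8%) had lower shares among the autosomes. Without receptor, defensin and keratin-associated families the X share was 47.6%, below every autosome, with chromosome 14 next at 48.3%. Among genes at CPM 1 or more, 447 X-linked genes had a median CPM of 30.1 against 30.8 for autosomal genes. The ratio was 0.977 (bootstrap 95% interval over genes 0.794 to 1.21), and 9 of 19 autosomes lay below the X. Per kilobase of exon the ratio was on the other side of 1, at 1.12, still inside that interval, and 16 of 19 autosomes lay below the X (12 per kilobase among overlap-free genes). Each autosome was set against the others in the same way. Chromosome 8 had a ratio of 1.66 (1.45 to 1.89; 616 genes) and chromosome 16 a ratio of 1.65 (1.32 to 1.85; 375 genes). Chromosome 7 was lowest at 0.703 (0.580 to 0.806), and chromosome 13 was at 0.773 (0.653 to 0.884). The values pool both alleles, so the ratio does not separate the 129 X chromosome from the castaneus one.

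**Figure D2:**
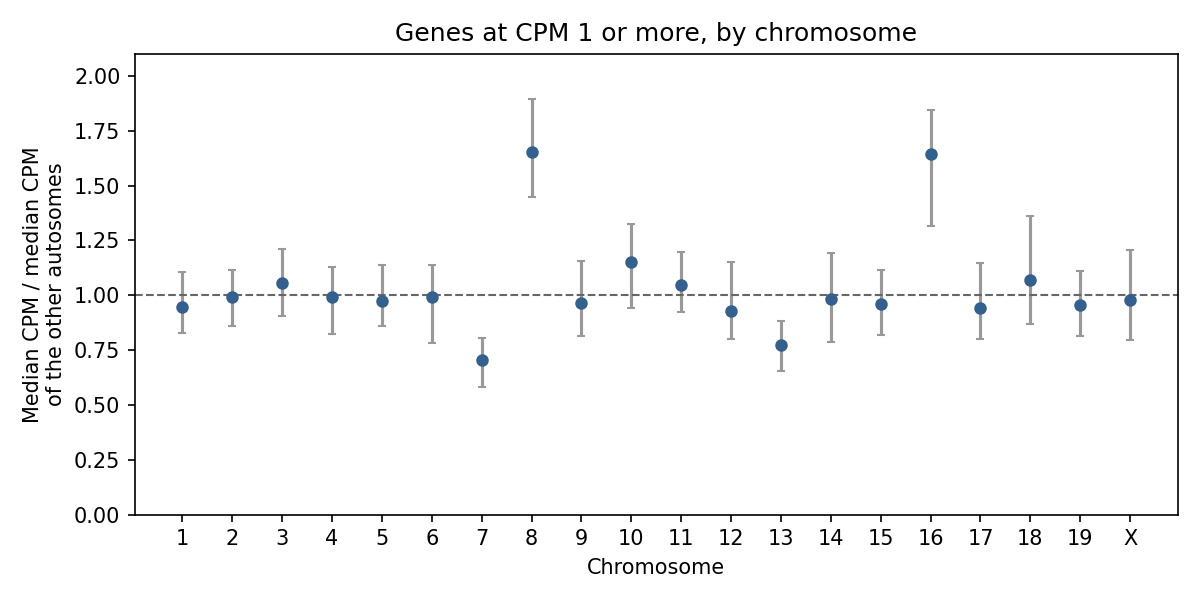
Ratio of the median CPM of the genes of each chromosome to that of the other autosomes (for the X, all autosomes), genes at CPM 1 or more. Bars are bootstrap 95% intervals over genes and the dashed line is a ratio of 1. Chromosomes 8 (1.66) and 16 (1.65) stand above the others, chromosomes 7 (0.703) and 13 (0.773) lie below, and the X is at 0.977.

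The title of the series raises the question whether regions near nuclear bodies are transcribed, and a pair of comparisons by position addressed it. Genes on chromosomes 12, 15, 16, 18 and 19, which carry ribosomal DNA in mouse and so meet at the nucleolus, were detected at CPM 1 or more in 59.7% of cases on average. On the other 14 autosomes the share was 55.3%. The difference of 4.41 percentage points had a two-sided exact permutation p of 0.114 over all choices of 5 of 19 autosomes. It was 2.65 points without receptor, defensin and keratin-associated families (exact permutation p 0.283) and 6.68 among overlap-free genes (exact permutation p 0.0548). Genes in the first 10 Mb of gene-bearing sequence on each autosome, nearest to the centromere, were detected in 58.5% of cases as a mean over the 19 autosomes, against 56.5% for the rest. Over pooled genes the order turned, with 55.2% of 1533 genes near the centromere and 56.0% of 19274 others. The difference of 2.05 percentage points had a two-sided exact sign-flip permutation p of 0.575 over 524288 arrangements, and the share near the centromere was lower on 9 of 19 autosomes. On chromosome 14 the first 10 Mb gave 10.1% against 51.2%, and on chromosome 18 it gave 80.9% against 53.6%. Over the first 20 Mb the mean difference turned to -2.24 points, with an exact permutation p of 0.495. Over the first 10 Mb without the same families it was 0.0788 points (exact permutation p 0.984). Neither comparison passed 0.05, and position stands here for nuclear location, which was not measured in these libraries.

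Genes were not listed evenly with respect to their neighbours, which bears on absences such as Sox2, Srsf2 and G6pdx. Apart from receptor, defensin and predicted-gene families, 76.7% of genes that overlap no other gene were listed, and 88.5% of those with partial overlap. Of 941 genes nested wholly inside another gene, 63 were listed, or 6.70%.

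**Figure D3:**
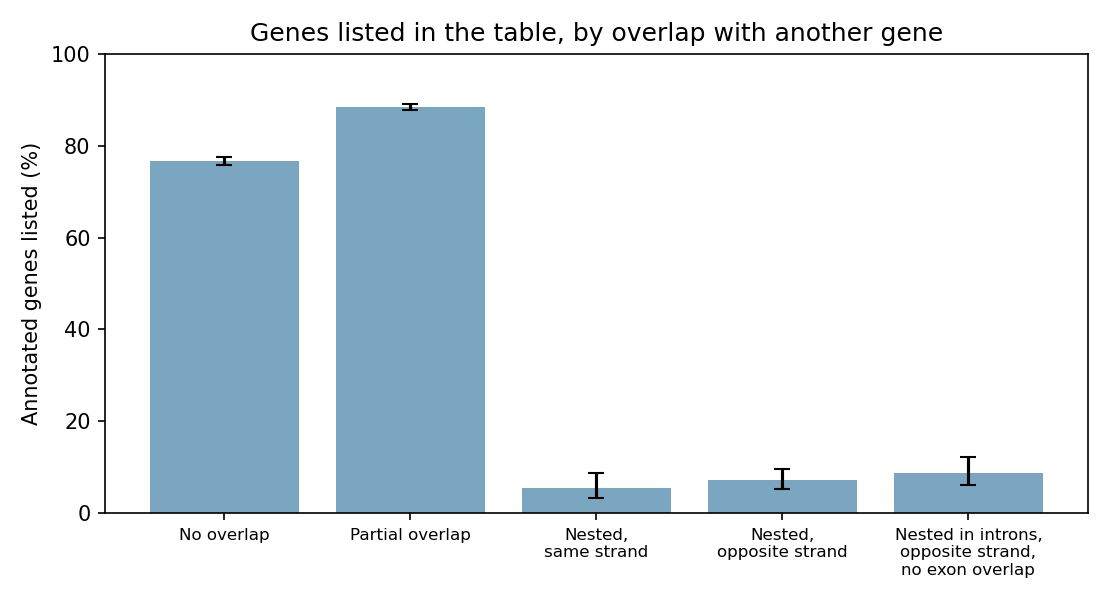
Percentage of annotated protein-coding genes listed in the table, by overlap with any other annotated gene. Error bars are Clopper-Pearson 95% intervals, which cover counting error only. Genes without overlap (76.7%) and with partial overlap (88.5%) were listed far more often than nested genes on the same strand (5.56%) or the opposite strand (7.19%).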

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

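The overlap-free, unlisted-at-0 and pooled-gene settings, and all for LIF against ERK targets, were chosen after the data were seen. The number of detected genes ranged from 9720 (overlap-free) to 12866 (CPM 0.5). The naive minus formative difference stayed between 3.11 and 3.59, and that of LIF and ERK targets between 2.88 and 4.64. With unlisted members at 0, a setting that lowers the comparison set, the core and naive against lineage difference was 6.95 and the nuclear list difference 5.33. It also brought the endoderm and trophoblast medians close to that of all genes (-0.36 and -0.055). Of 40 list medians, 5 changed sides of all genes. With unlisted members at 0, zinc finger (1.26), germline (1.32) and ERK target genes (0.20) turned from below to above. Formative and primed genes (-0.41 and -0.13) and Wnt targets (-0.21 and -0.12) turned below at CPM 1 or more and among overlap-free genes. Of these lists, all but the zinc finger genes had a main interval that includes 0. Limiting to genes at CPM 1 or more, which removes low genes from the comparison set, gave 2.20 for the nuclear lists. The share of the 7 large families detected fell to 0.70% at CPM 5, a stricter minimum. The X to autosome ratio ranged from 0.80 without a minimum to 1.12 per kilobase. The centromere difference turned to -2.24 over 20 Mb, to -0.812 over pooled genes and to -0.045 on median log2(CPM + 1); the cause was not tested. The ribosomal DNA chromosome difference kept its sign, with exact permutation p from 0.0548 (overlap-free) to 0.464 (median level). Among the values for single lists and gene groups, 129 stayed within their main intervals, 77 moved outside and 1 reversed. With unlisted members at 0, 33 of the 40 list medians moved outside and 1 reversed. Library-wise settings (each replicate left out, TMM or DESeq2 size factors, replicate agreement and dispersion) were not run, as there was 1 column. Leaving out mitochondrially encoded genes moved nothing, since none was listed. No paired analysis was possible because there was 1 group. Depth limits low genes: at CPM 1 the Poisson half-width was 64.5% of the value.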

Other observations

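The tests of counting over gene spans, of strand, of silent nested genes, of shared sequence with exon length held constant, and of exon length and overlap on chromosomes 8 and 16 were chosen after the results were seen. The wider interval for list members on chromosomes 8 and 16 was also added after the result was seen.

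Stress, p53 and cycle genes were expressed at high levels. Genes of the integrated stress response and of serine synthesis had a median CPM of 196 over 13 listed members, led by Asns, which makes asparagine, with 15455 counts, Psat1 with 6630 and Atf4 with 4140. Ddit3, which encodes the stress factor CHOP, was lowest with 169. Targets of p53 had a median CPM of 111, all 12 at CPM 1 or more, led by the cycle inhibitor gene Cdkn1a with 4501 counts, Ccng1 with 3026 and Mdm2 with 2097. Cell cycle genes had a median CPM of 313, led by Mcm6 with 6158 counts, Top2a with 6011 and Mcm4 with 5518, and lowest at Ccne2 with 59. Housekeeping genes had a median CPM of 1390, but Gapdh had 2153 counts, with 24.7% of its 50-base words found in genes elsewhere. Eef1a1, which had the highest count, had 37.6%, and Tuba1b, with 1775 counts, had 66.0%. These shares cover the words of all annotated transcripts of each gene. Gapdh shared words with 218 genes elsewhere, Eef1a1 with 19 and Tuba1b with 16. The cause of the low Gapdh count was not tested. Of 395 annotated Zfp zinc finger genes, 318 were at CPM 1 or more, with a median CPM of 9.73 over the listed members.

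Genes nested inside another gene were nearly missing from the table. Apart from receptor, defensin and predicted-gene families, 76.7% of 9186 genes without overlap were listed (Clopper-Pearson 95% interval 75.8 to 77.6), against 6.70% of 941 nested genes. Shortness is argued against, because non-overlapping genes matched on exon length were listed 66.7 points more often (63.7 to 69.6), and loss on the same strand alone too, since opposite-strand nested genes were listed at 7.19%. Silence is argued against by broadly expressed lists, in which 1 of 9 nested members was listed (Rpl7l1, but not Rpl13, Cox4i1 or Srsf2) and 376 of 381 others, a gap of 87.6 points (48.7 to 99.3). Counting over whole gene spans without strand may be the source, as genes nested in introns on the opposite strand with no exon overlap were listed at only 8.78% (6.04 to 12.2). Row order also followed count per base of gene span (Spearman rho 0.9999) more closely than count per exonic base (0.920). That bears on the length used for ordering and not directly on the counting. If whole spans were counted, intronic reads are in the counts, and values per kilobase of exon divide by too short a length. Silence was the only biological explanation tested.

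Ribosomal protein genes ranged from 0.971 counts per kilobase of exon for Rpl24 to 46096 for Rplp1, with a median of 6164 over 80 genes. Overlap with neighbours may account for part of the spread. Across genes, which are not independent replicates, Spearman rho with the share of exonic bases under another gene was -0.280 (-0.490 to -0.048). Exon length enters both of these measures, and rho with exon length held constant was not computed for overlap. Rpl24 and Rps10, with 1 and 9 counts, had over 0.9 of their exonic bases under another gene. Reads shared with copies elsewhere would lower the count, but rho with shared 50-base words was 0.358 (0.110 to 0.572). That test decides little, because exon length enters both measures, and with exon length held constant rho was 0.223 (-0.043 to 0.469), so shared reads stay open.

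For the higher medians of chromosomes 8 and 16, exon length and overlap are argued against as the whole cause. The lower of the ratios for these chromosomes was 1.52 per kilobase of exon (1.21 to 1.74) and 1.71 among overlap-free genes (1.47 to 2.04). Length of the gene span was not tested. Chance spread of single genes between chromosomes is argued against by 1000 shuffles of genes over chromosomes, in which the highest ratio was 1.42. The shuffles treat neighbouring genes as independent, so they cannot decide on spread that neighbours share. Chromosomes 7 (0.703, 0.580 to 0.806) and 13 (0.773, 0.653 to 0.884) also lay away from 1. Fewer tissue-restricted genes there stay open: ratios fell from 1.55 and 1.78 at the 25th percentile to 1.27 (1.101 to 1.63) and 1.22 (0.990 to 1.63) at the 90th on chromosomes 8 and 16, so an interval that includes 1, which it needs, was met on chromosome 16 only. Against it, 14 members of broadly expressed lists lay 0.54 above their lists on the log2 scale, 10 of them higher, but their interval of 0.018 to 0.894 became -0.164 to 0.856 when the list medians were resampled too. Extra copies of these chromosomes in some cells stay open, as all ratios over parts and percentiles lay between 1.22 and 1.83. Extra copies would shift all percentiles alike, whereas the ratios fell toward the 90th percentile, though with overlapping intervals. On chromosome 16 the 90th percentile and the last part had intervals that include 1. No DNA or karyotype was analysed here, so these values do not decide it.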
